A study of Mus musculus with 24 samples.

How the data were processed

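The series compared brain RNA of R6/2 mice with that of wild-type littermates. R6/2 is a transgenic mouse line that carries the first exon of the human huntingtin gene with an expanded CAG repeat and is widely used as a model of Huntington's disease. Per the labels, the mice were on a mixed C57Bl/6 and CBA background, and polyadenylated RNA from cortex or striatum was taken at 8 or 12 weeks of age. The 24 libraries fell into 8 groups of 3, each a tissue, an age and a genotype. Per the labels' protocols, the RNA was selected on oligo(dT) beads, fragmented and made into strand-specific, paired-end libraries with dUTP marking. Reads were short and of different lengths on the Genome Analyzer and HiSeq instruments, and the labels do not say which library ran on which. Samples were grouped by the tissue, age and genotype in their labels. Nothing states that the 3 samples of a group were separate animals, so p-values measure the spread between these samples, which may be partly technical.

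The authors deposited a file per library with a whole-number read count, a gene length and an RPKM value (reads per kilobase of gene, scaled to library size) for each of 18669 Entrez gene IDs. They also deposited a table of RPKM for each tissue and age, whose values lay within 0.005 of those in the library files. The tables held 12 columns that belong to no sample (gene names and descriptions), and these were used only for symbols. Per the submitters' processing notes, Bowtie, DESeq and the mouse build mm9 were used, and no version or role is named there. The counting program, its strand setting and its treatment of reads that fit several genes are not given in the sources used here. Values of near-identical paralogs and of overlapping genes are therefore uncertain. The deposited RPKM divided each count by a library total larger than the sum of counts in genes. Counts in genes made up 25.7 to 28.3% of that total in 5 of the striatal libraries at 8 weeks, 42.9% in the other (wild type replicate 1), and 44.2 to 59.7% in the libraries of the other groups. In 3 libraries (R6/2 cortex at 8 weeks replicate 3, R6/2 cortex at 12 weeks replicate 2 and R6/2 striatum at 12 weeks replicate 3) the deposited gene lengths were shorter than in the other 21 by 4 to 760 bases, and 96.4% of the differences were multiples of 4.

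Gene symbols were taken through the Entrez IDs from the RefSeq gene table of GRCm38.p6, which matched 18594 of 18669 IDs; the other 75 keep the symbol of the deposited tables. That table was used for names alone, and no coordinates are printed because its build differs from mm9. The deposited tables call Htt Hdh (gene ID 15194), Drd1 Drd1a (13488), Penk Penk1 (18619), Kdm5c Jarid1c (20591), Gm12695 LOC620779 (620779) and Kcnh4 LOC380728 (380728). No pair of replicate libraries agreed within counting noise. The chi-square per degree of freedom between replicates of a group ran from 8.00 (wild-type striatum at 8 weeks, replicates 2 and 3) to 208 (R6/2 striatum at 12 weeks, replicates 1 and 3). None was therefore merged as repeat sequencing of the same library, and each library counted as 1 replicate. This check cannot tell whether the libraries came from separate animals.

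The deposited counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) in R 4.3.3, on genes with a mean RPKM of at least 0.5 over the compared samples. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each of the 4 genotype comparisons was fitted on its own 6 libraries. The age by genotype and tissue by genotype interactions used 12 libraries each, and wild-type striatum was compared with wild-type cortex at each age. The interactions and the tissue comparisons had been planned with limma 3.58.1 on log2(RPKM + 0.5). Since the files held counts, edgeR took its place, and limma's counts stand beside the results. Fold changes are R6/2 relative to wild type unless stated, standard errors are the absolute log2 fold change over the square root of the quasi-likelihood F, and levels are RPKM as mean ± SD over 3 libraries. Library totals in genes ran from 7.09 to 47.7 M counts. Fragments carried no molecular identifiers, so floors and intervals cover counting error alone. Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group.

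Lists of genes fixed beforehand (524 entries in 35 lists, of which 503 matched and 21, Xist among them, are not analysed here) were tested with camera, which asks whether a list moved relative to the other genes, on TMM-scaled log2 CPM (counts scaled to library size) with a prior count of 2. The preset correlation between genes was 0.01, at least 3 members had to pass the expression minimum, and p-values were adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes moved on balance in a direction, were run beside it. The lists covered markers of striatal projection neurons (shared, direct pathway and indirect pathway), cortical projection neurons, interneurons, astrocytes, reactive astrocytes, microglia, myelinating oligodendrocytes, oligodendrocyte precursors, vessels, meninges, choroid plexus, thalamus and blood. They also covered immediate early genes, neuropeptides, ion channels and receptors, calcium signalling, cholesterol synthesis, heat shock, the unfolded protein response, mitochondrial respiration, histone H3K4 methyltransferases and demethylases, REST targets, Hox and other developmental regulators, the p53 and interferon responses, the circadian clock and histones without a poly(A) tail. Genes enriched at least 4-fold in a tissue were taken from the wild-type libraries of the other age, so that no library both chose and tested a set.

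The tests, the samples in each, the lists and the rule for named genes were fixed before the data were examined. The rule named, for each genotype comparison, the 8 largest rises and the 8 largest falls among genes that passed, with a mean RPKM of at least 1 and no overlap between genotypes. It added up to 4 members of each list with the smallest adjusted p, Htt, Gm12695, Ppp1r1b, Drd1, Drd2, Penk, Pde10a, Bdnf, Gfap, Kdm5c and the sex-linked genes in every comparison, and the 5 genes with the smallest adjusted p in each interaction. Some list members that the rule names are not reported here. Alternatives fixed in advance were limma at pseudocounts of 0.1 and 1, no expression minimum or a minimum of 2 RPKM, median-of-ratios and quantile scaling, a single fit over 24 libraries, robust empirical Bayes, a minimum of 1.5-fold, DESeq2 1.42.0, a block for shared sample numbers and leaving out each library. Limma at a pseudocount of 0.5, the test first planned, was kept as an alternative. Alternatives chosen after seeing the data were scaling to the authors' library total, an offset for the deposited gene lengths, and a correction for GC content with or without gene length. The correction removed each library's trend (natural splines with 4 degrees of freedom, fitted on genes above the 25th percentile of expression). GC content came from the transcripts of GENCODE M21 through Biostrings 2.70.1 and was known for 99.8% of the 10742 genes checked. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

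The test was tried on simulated data drawn from the libraries' own means and totals with known changes. At 4-fold, edgeR recovered 84.8% of the changed genes for cortex at 8 weeks (11631 genes), 80.3% for striatum at 8 weeks (11109 genes), 98.5% for cortex at 12 weeks (11735 genes) and 84.8% for striatum at 12 weeks (11555 genes). At 2-fold it recovered 10.4%, 13.4%, 53.7% and 17.9% in the same order, with 6, 6, 9 and 14 false calls. When a GC trend was added to a single simulated library of each genotype, 4-fold recovery was 30.3%, 15.2%, 75.8% and 42.4%. With the GC and length correction it was 83.3%, 71.2%, 95.5% and 77.3%. A trend in wild-type libraries alone, as found in cortex at 8 weeks, was not simulated, so false calls from such a trend were not measured.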

Results

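Cortex and striatum of R6/2 mice and wild-type littermates were profiled by mRNA sequencing at 8 and 12 weeks of age, with 3 libraries for each of the 8 combinations. Counts in genes ran from 7.09 to 47.7 M per library, and the striatal libraries at 8 weeks were among the smallest (7.79 to 13 M in R6/2, 7.09 to 9.04 M in wild type). Levels are RPKM as mean ± SD over 3 libraries, and adjusted p values of single genes come from edgeR.

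The genotype labels held in every library. Gm12695, the gene into which the R6/2 transgene is known to have inserted, had 24 to 193 counts in each of the 12 R6/2 libraries (852 in total), and the 12 wild-type libraries held 8 counts between them. In cortex at 12 weeks it lay at 1.32 ± 0.161 RPKM in R6/2, with 325 counts against 0 in wild type (at least 68.7-fold, adjusted p = 0.00307). Mouse Htt was read in all libraries and differed with genotype in none of the comparisons (log2 fold change 0.22, SE 0.164, adjusted p = 0.525 in cortex and -0.59, SE 0.302, adjusted p = 0.373 in striatum at 12 weeks). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no counts apart from a single Ddx3y read in a wild-type library, so the sex-linked list was not tested, and no library showed RNA of a male.

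In striatum at 12 weeks, R6/2 samples had less RNA of many genes that mark striatal projection neurons, the cells that die first in Huntington's disease. Scn4b, which encodes a sodium channel subunit of these neurons, fell from 398 ± 96.9 to 29.3 ± 17.7 RPKM (log2 fold change -3.89, SE 0.398, adjusted p = 0.00144, n = 3 per group). Pde10a, a phosphodiesterase that breaks down cyclic nucleotides behind the dopamine receptors, fell from 138 ± 16.5 to 23.9 ± 9.32 RPKM (log2 fold change -2.70, SE 0.312). Dopamine receptors of both output pathways fell as well, Drd1 by 3.67-fold (26.2 ± 7.15 against 86.9 ± 19.0 RPKM, adjusted p = 0.00830) and Drd2 by 4.66-fold (11.3 ± 5.12 against 49.5 ± 23.0 RPKM, adjusted p = 0.00950). The interferon-induced gene Ifit1 rose at the same time, at 7.65 ± 3.07 against 0.417 ± 0.410 RPKM.

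Of 27 genes shared by both types of striatal projection neuron, 24 fell and none rose (27 lower when adjusted over the list alone). Shared striatal genes had a median of -1.68 log2 units, with camera adjusted p = 1.12e-36 and adjusted p = 0.0853 with an estimated correlation. They included Ryr1, a calcium release channel (0.433 ± 0.162 against 3.13 ± 0.12 RPKM, log2 fold change -3.03, SE 0.323), Arpp19 (-2.45, SE 0.267), Adcy5 (34.7 ± 12.9 against 170 ± 41.5 RPKM) and Ppp1r1b, the DARPP-32 phosphatase inhibitor (219 ± 156 against 1252 ± 673 RPKM, log2 fold change -2.63, SE 0.501, adjusted p = 0.0172). Among 6 markers of indirect pathway neurons, which project to the external pallidum, 5 fell (6 when adjusted over the list alone). Indirect pathway genes had a median of -2.56 log2 units, with camera adjusted p = 1.23e-09 and adjusted p = 0.0853 with an estimated correlation. They included Penk, the enkephalin precursor, with 6.22-fold (log2 fold change -2.64, SE 0.315, adjusted p = 0.00209), Adora2a (16.2 ± 9.95 against 89.7 ± 25.6 RPKM) and Gpr6 (-2.52, SE 0.455). Of 8 markers of direct pathway neurons, 4 fell, also when adjusted over the list alone. Direct pathway genes had a median of -0.79 log2 units, with camera adjusted p = 0.000975 and adjusted p = 0.369 with an estimated correlation. Chrm4, a muscarinic receptor, fell most (6.03 ± 1.84 against 25.7 ± 7.57 RPKM, log2 fold change -2.20, SE 0.282), and Pdyn (-1.54, SE 0.376, adjusted p = 0.0437) and Slc35d3 (-1.12, SE 0.282, adjusted p = 0.0493) passed by a small margin.

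**Figure D1:**
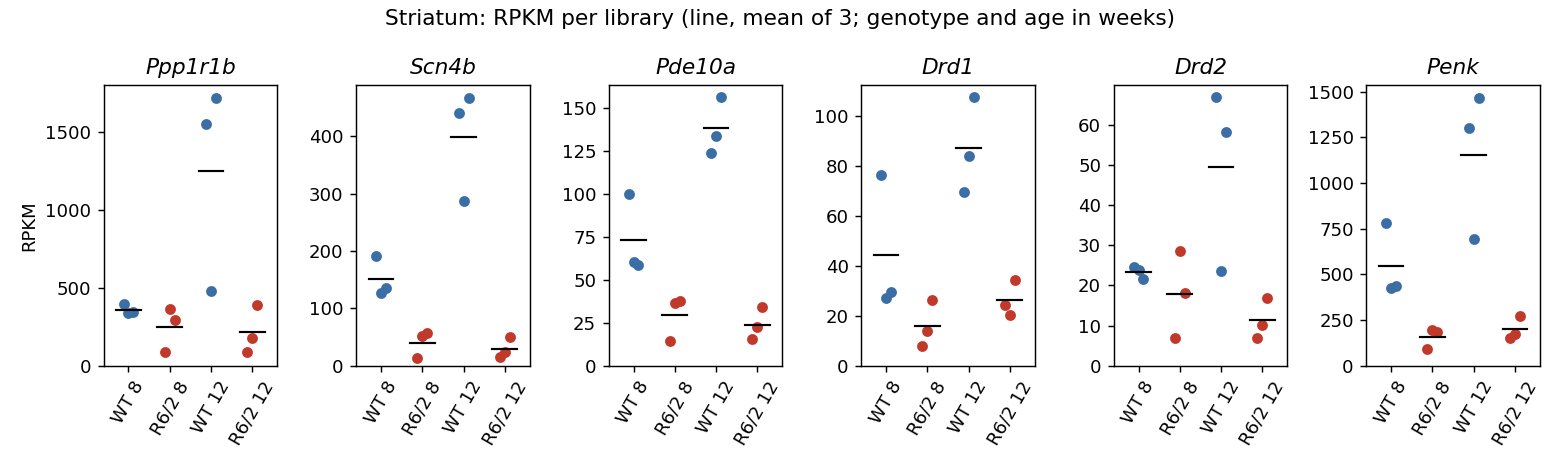
RPKM (vertical axis) of Ppp1r1b, Scn4b, Pde10a, Drd1, Drd2 and Penk in striatum of wild-type (blue) and R6/2 (red) mice at 8 and 12 weeks; each point is a library and each line the mean of 3. At 12 weeks the R6/2 means of Scn4b and Pde10a lie at 29.3 and 23.9 RPKM against 398 and 138 in wild type. RPKM should be compared within an age only. Counts in genes made up 25.7 to 42.9% of the authors' library total at 8 weeks and 44.2 to 57.9% at 12 weeks.

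The largest falls in this tissue went to genes of varied function. Gpx6, a glutathione peroxidase, was almost absent from R6/2 (0.0663 ± 0.115 against 8.28 ± 5.28 RPKM, 17 against 942 counts, log2 fold change -6.38, SE 0.809, adjusted p = 0.00172). Egr2, an immediate early transcription factor, fell 28.9-fold (log2 fold change -4.85, SE 0.644). Kcnh4, a potassium channel, fell from 4.83 ± 0.902 to 0.555 ± 0.248 RPKM, and Sec14l3 (-3.76, SE 0.646), Npsr1 (-3.55, SE 0.581) and Clec12a (-3.49, SE 0.587) also fell. Immediate early genes report recent neuronal activity, and 7 of 19 fell (13 when adjusted over the list alone), among them Egr1 (30.6 ± 10.3 against 81.0 ± 13.7 RPKM), Egr3 (-2.51, SE 0.472) and Per1 (-2.01, SE 0.370). Immediate early genes had a median of -1.55 log2 units, with camera adjusted p = 7.8e-11 and adjusted p = 0.238 with an estimated correlation.

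Of 22 genes of calcium signalling, 13 fell (17 when adjusted over the list alone), including the calcium release channel Itpr1 (34.7 ± 11.2 against 131 ± 14.8 RPKM), Pcp4 (-1.83, SE 0.296), Camk4 (-1.55, SE 0.262) and Cacna2d3 (-1.38, SE 0.25). Calcium genes had a median of -1.23 log2 units, with camera adjusted p = 3.57e-18 and adjusted p = 0.0894 with an estimated correlation. Of 18 potassium channel genes, 6 fell and Kcnip1 rose (12 lower and 2 higher when adjusted over the list alone), with Kcnab1 at 59.3 ± 5.92 against 169 ± 21.8 RPKM and Kcnip1 at 1.48 (SE 0.357, adjusted p = 0.0420). Potassium channels had camera adjusted p = 1.13e-07 and adjusted p = 0.0853 with an estimated correlation. Among glutamate receptor genes Grm3 (-1.56, SE 0.269) and Grm5 (-1.59, SE 0.292) fell, and the kainate receptor gene Grik1 rose from 0.698 ± 0.310 to 4.83 ± 2.32 RPKM (9 lower and 1 higher of 15 when adjusted over the list alone). Glutamate receptors had camera adjusted p = 0.00024 and adjusted p = 0.135 with an estimated correlation. Gabrd, a GABA receptor subunit, fell (9.14 ± 5.54 against 41.7 ± 9.96 RPKM), while the 14 GABA receptor genes did not pass as a list (camera adjusted p = 0.764). Of 16 clock genes 6 fell (7 when adjusted over the list alone), including Dbp (-2.05, SE 0.472), Nr1d1 (-1.45, SE 0.312) and Hlf (-1.16, SE 0.246). Clock genes had a median of -0.95 log2 units, with camera adjusted p = 2.01e-06 and adjusted p = 0.0853 with an estimated correlation. The hour of tissue collection is not given in the sources used here.

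All 10 interferon response genes lay above wild type and 6 passed (8 when adjusted over the list alone). Interferon genes had a median of 1.69 log2 units, with camera adjusted p = 4.76e-09 and adjusted p = 0.0894 with an estimated correlation. Usp18, which restrains interferon signalling, rose 16.8-fold (2.16 ± 0.388 against 0.103 ± 0.179 RPKM, adjusted p = 0.0183), Ifit1 16.4-fold and Oasl2 by 3.38 log2 units (SE 0.611). Of 15 astrocyte genes, 2 fell (3 when adjusted over the list alone), the glutamate transporter Slc1a2 (22 ± 6.88 against 84.4 ± 34.1 RPKM) and Slc4a4 (-1.09, SE 0.242). Astrocyte genes had camera adjusted p = 0.00704 and adjusted p = 0.400 with an estimated correlation. None of 16 myelin genes passed, although 15 lay lower (none when adjusted over the list alone). Myelin genes had a median of -0.64 log2 units, with camera adjusted p = 7.2e-05 and adjusted p = 0.536 with an estimated correlation. The 20 cholesterol synthesis genes shifted little (no gene passed; median -0.24, camera adjusted p = 0.0482, and adjusted p = 0.383 with an estimated correlation).

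Several of the largest rises came from genes that striatum hardly expresses, and their levels differed widely between R6/2 libraries. Irs4, an insulin receptor substrate, had RPKM of 6.73, 0.590 and 0.391 in R6/2 replicates 1, 2 and 3 (0.0462 ± 0.0358 in wild type, log2 fold change 5.65, SE 1.28, adjusted p = 0.0295). Arhgap36 had 12.3, 3.25 and 0.173 (log2 fold change 5.49, SE 1.36), AW551984 32.8, 10.2 and 2.35 (5.42, SE 0.923), and Dgkk 9.13, 1.93 and 0.977 (4.93, SE 0.951). Glra3, a glycine receptor subunit, rose more evenly to 2.19 ± 0.831 RPKM (22.8-fold, adjusted p = 0.0169). Slc17a6, the vesicular glutamate transporter of thalamus and hypothalamus, had 25.7, 16.4 and 5.81 RPKM against 1.29 ± 1.08 (log2 fold change 3.50, SE 0.685, adjusted p = 0.0183), and Calb2 had 37.9, 15.6 and 5.75 against 2.53 ± 1.17 (2.85, SE 0.684, adjusted p = 0.0404). Of the 7 thalamus markers these 2 rose, also when adjusted over the list alone. Thalamus markers had a median of 0.62 log2 units, with camera adjusted p = 0.0482 and adjusted p = 0.400 with an estimated correlation. R6/2 replicate 1 had the most Irs4, Arhgap36, AW551984, Dgkk, Slc17a6 and Calb2. It also had the least Ppp1r1b (84.9 RPKM, against 391 in replicate 3) and a GC correlation of -0.570 (-0.266 and -0.00153 in replicates 2 and 3).

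The remaining lists did not pass with camera in this comparison. Neuronal and glial lists were cortical projection neurons (adjusted p = 0.825), interneurons (0.343, with Reln lower at -1.24 and Calb2 higher), neuropeptides (0.162, with Penk and Pdyn lower and Adcyap1 higher at 3.04, SE 0.653), reactive astrocytes (0.523), microglia (0.839) and oligodendrocyte precursors (0.720). Lists of other cells were vessels (0.720), meninges (0.920), choroid plexus (0.839) and blood (0.839). Lists of cell function were heat shock (0.371), unfolded protein response (0.610), mitochondrial respiration (0.339), H3K4 methyltransferases (0.839), H3K4 demethylases (0.825, where median and mean differed in sign), REST targets (0.920, with Stmn2 higher at 1.22 and Chrm4 lower), p53 response (0.920, with Cdkn1a lower at -1.62) and histones without a poly(A) tail (0.720). Bdnf (0.36, SE 0.457), Gfap (-0.62, SE 0.597) and Kdm5c (-0.19, SE 0.264) did not pass.

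Across all 11587 genes tested in striatum at 12 weeks, 102 were higher and 282 lower in R6/2 with edgeR. An unadjusted p under 0.05 was found for 1885 genes where 579 were expected, and 380 of the 384 differed at least 2-fold. DESeq2 gave 231 higher and 534 lower, limma 4 and 6, and scaling to the authors' library total 86 and 129, a smaller share of falls. Groups did not overlap for 2709 genes (23.4%, where 10% were expected by chance). Without R6/2 replicate 2 the test passed 42 genes, without R6/2 replicate 1 127, and without wild type replicate 3 124. After removal of each library's trend on GC content and length it passed 258 higher and 472 lower (730 in all, 369 of them among the 384).

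Genes at least 4-fold enriched in striatum over cortex, taken from wild-type libraries at 8 weeks, gave the broadest view of the loss. Of the 139 tested, 58 fell and 2 rose at 12 weeks (41.7% fell, against 2.43% of all genes), with a median log2 fold change of -1.25 (quartiles -2.08 and -0.33; camera p = 1.94e-30, p = 0.00768 with an estimated correlation, fry p = 0.000697). The rises were Gpr101 (3.16, SE 0.632) and Rpgrip1 (3.07, SE 0.728), both named after their values were seen. The 55 cortex-enriched genes did not pass as a set (4 higher, namely Glra3, Adcyap1, Tafa1 and, named after its value was seen, Syt17 at 2.07; 0 lower, median -0.04, camera p = 0.167, p = 0.741 with an estimated correlation).

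In cortex at 12 weeks the R6/2 samples had less RNA of several activity-regulated genes and neuropeptides, and more of several interferon response genes. Arc, which tunes synapses after activity, fell from 64.8 ± 3.61 to 18.4 ± 3.40 RPKM (log2 fold change -1.96, SE 0.167, adjusted p = 0.00064, n = 3 per group). Lamp5, of superficial layer neurons, fell from 87.4 ± 15.9 to 20.9 ± 6.64 RPKM (-2.22, SE 0.241, adjusted p = 0.0014), and somatostatin (Sst) from 250 ± 129 to 68.6 ± 11.2 RPKM (-1.99, SE 0.308, adjusted p = 0.00492). Bdnf, the trophic factor that cortex supplies to striatum, fell from 7.31 ± 1.25 to 4.47 ± 0.644 RPKM (-0.86, SE 0.191, adjusted p = 0.0277).

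All 19 immediate early genes lay lower in R6/2 cortex and 8 fell (16 when adjusted over the list alone), with Egr2 at -2.32 (SE 0.315), Npas4 at -1.48 (SE 0.236) and Egr3 at -1.66 (SE 0.270). The immediate early list had a median of -0.97 log2 units, with camera adjusted p = 1e-13 and adjusted p = 0.116 with an estimated correlation. All 16 neuropeptide genes lay lower and 9 fell (10 when adjusted over the list alone), including Cck (139 ± 21.8 against 285 ± 44.3 RPKM, -1.18, SE 0.153) and Penk (-1.40, SE 0.337, adjusted p = 0.0380). Neuropeptides had a median of -1.07 log2 units, with camera adjusted p = 3.24e-11 and adjusted p = 0.0618 with an estimated correlation. All 14 interneuron genes lay lower and 5 fell (8 when adjusted over the list alone), including Vip (6.97 ± 0.676 against 15.6 ± 3.63 RPKM), Gad1, which makes GABA (-0.88, SE 0.174), and Crh (-1.50, SE 0.299). Interneuron genes had a median of -0.77 log2 units, with camera adjusted p = 2.73e-07 and adjusted p = 0.0669 with an estimated correlation. Of 19 cortical projection neuron genes 5 fell (10 when adjusted over the list alone). Projection neuron genes had a median of -0.52 log2 units, with camera adjusted p = 4.52e-07 and adjusted p = 0.236 with an estimated correlation. Camk2a, the kinase of excitatory synapses, fell from 509 ± 11.0 to 279 ± 3.37 RPKM (adjusted p = 0.00305), Nrn1 by 1.25 log2 units (SE 0.175) and Rasgrf2 by 0.86 (SE 0.155).

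Of the 27 shared striatal genes 5 fell (7 when adjusted over the list alone), with Ryr1 (0.456 ± 0.0549 against 2.12 ± 0.0370 RPKM, -2.36, SE 0.171, adjusted p = 0.000232), Scn4b (6.26 ± 1.75 against 26.1 ± 1.18 RPKM, -2.19, SE 0.199), Arpp19 (-1.50, SE 0.275) and Ppp1r1b (29.1 ± 12.0 against 75.4 ± 20.7 RPKM, -1.51, SE 0.274, adjusted p = 0.0110). Striatal genes had a median of -0.47 log2 units, with camera adjusted p = 2.83e-07 and adjusted p = 0.326 with an estimated correlation. Of 5 indirect pathway genes only Penk fell, also when adjusted over the list alone (camera adjusted p = 0.0163, and adjusted p = 0.412 with an estimated correlation). Drd1 (4.51 against 4.52 RPKM, -0.13, SE 0.338), Drd2 (-0.53, SE 0.580) and Pde10a (-0.48, SE 0.305) did not pass in cortex, nor did the direct pathway list (camera adjusted p = 0.265). Without R6/2 replicate 1 Drd1 was lower (-0.76, adjusted p = 0.0461).

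Of 22 calcium signalling genes 10 fell in cortex (18 when adjusted over the list alone), among them Itpka (21.4 ± 4.69 against 59.0 ± 6.01 RPKM, -1.61, SE 0.170), Camk1g (-1.10, SE 0.170) and Itpr1 (-0.81, SE 0.137). Calcium genes had a median of -0.71 log2 units, with camera adjusted p = 1e-13 and adjusted p = 0.116 with an estimated correlation. Of 18 potassium channel genes 5 fell (9 when adjusted over the list alone), including Kcnh4 (-2.49, SE 0.330), Kcnh3 (-1.24, SE 0.191) and Kcna1 (-0.89, SE 0.173). Potassium channels had camera adjusted p = 6.19e-07 and adjusted p = 0.150 with an estimated correlation. Grm3 (-0.95, SE 0.137) fell among 15 glutamate receptor genes (3 lower when adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.266 with an estimated correlation). Gabrd (9.18 ± 1.73 against 22.4 ± 5.47 RPKM) fell among 14 GABA receptor genes (1 lower when adjusted over the list alone; camera adjusted p = 0.00984, and adjusted p = 0.412 with an estimated correlation). Of 16 clock genes 8 fell (9 lower and 1 higher when adjusted over the list alone), with Dbp (4.35 ± 1.76 against 13.1 ± 1.36 RPKM), Nr1d1 (-1.05, SE 0.156), Bhlhe40 (-1.19, SE 0.187) and Hlf (-0.95, SE 0.164). Clock genes had a median of -0.77 log2 units, with camera adjusted p = 1.2e-06 and adjusted p = 0.161 with an estimated correlation.

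Of 15 astrocyte genes 7 fell in R6/2 cortex (10 when adjusted over the list alone), among them Fgfr3 (-0.92, SE 0.169), Aldoc (-0.92, SE 0.203) and Glul, which recycles glutamate (266 ± 78.0 against 476 ± 71.1 RPKM). Astrocyte genes had a median of -0.73 log2 units, with camera adjusted p = 1.62e-07 and adjusted p = 0.266 with an estimated correlation. Vim (11.0 ± 2.74 against 4.85 ± 0.736 RPKM, 1.05, SE 0.206, adjusted p = 0.0161) and Serpina3n (1.01, SE 0.254, adjusted p = 0.0472) rose, while Gfap did not (-0.31, SE 0.255) and the reactive astrocyte list did not pass (camera adjusted p = 0.378). Of 16 myelin genes 3 fell (7 when adjusted over the list alone), Mal (22.3 ± 4.44 against 41.2 ± 6.71 RPKM), Cldn11 (-0.83, SE 0.156) and Ugt8a (-0.64, SE 0.146). Myelin genes had a median of -0.54 log2 units, with camera adjusted p = 4.01e-05 and adjusted p = 0.329 with an estimated correlation. Of 20 cholesterol synthesis genes 3 fell (6 when adjusted over the list alone), including Cyp51 (-0.77, SE 0.148) and Insig1 (-0.69, SE 0.176). Cholesterol genes had a median of -0.41 log2 units, with camera adjusted p = 2.5e-05 and adjusted p = 0.150 with an estimated correlation.

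**Figure D2:**
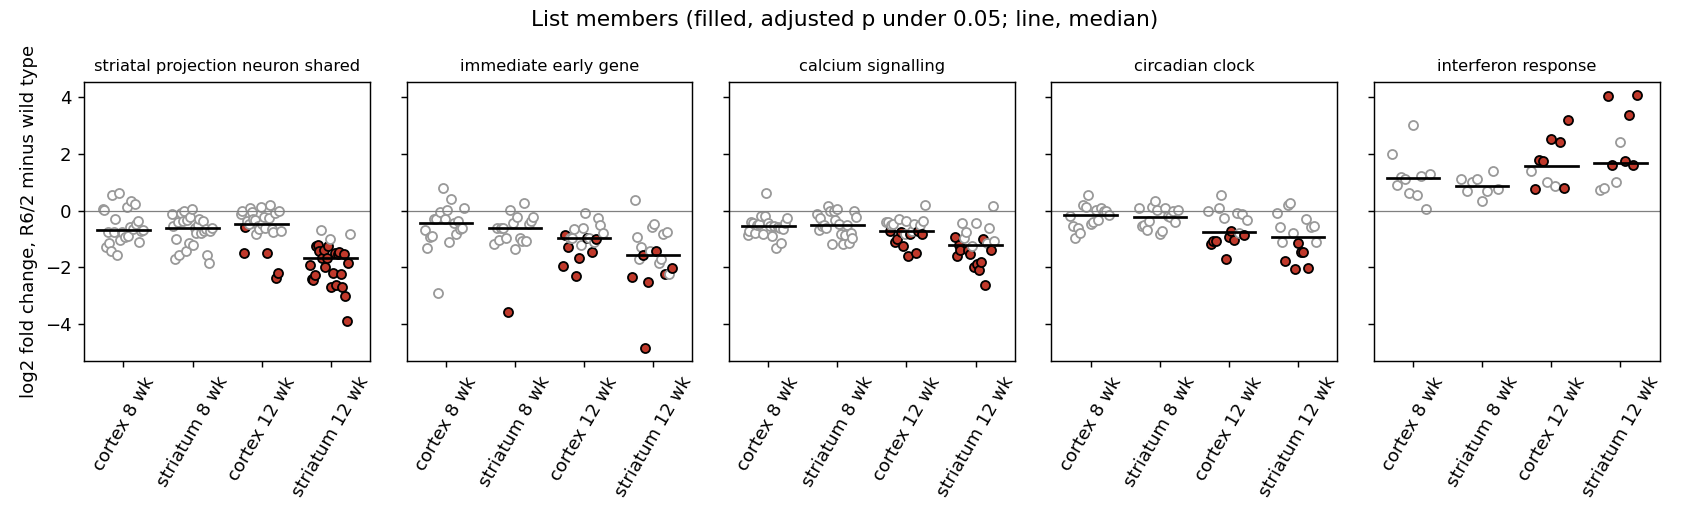
Log2 fold change (R6/2 over wild type, vertical axis) of the members of 5 gene lists, for each tissue and age; each point is a gene, filled where the adjusted p from edgeR was under 0.05, and the line is the list's median. In striatum at 12 weeks the median is -1.68 for shared striatal genes and 1.69 for the interferon response.

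All 10 interferon response genes lay higher in cortex too and 7 passed (10 when adjusted over the list alone). Interferon genes had a median of 1.58 log2 units, with camera adjusted p = 1e-13 and adjusted p = 0.0669 with an estimated correlation. Usp18 rose 9.08-fold (2.20 ± 0.728 against 0.208 ± 0.111 RPKM, adjusted p = 0.00492), the transcription factor Irf7 5.73-fold (adjusted p = 0.00492), Oasl2 by 2.43 log2 units (SE 0.287), Ifit1 3.46-fold (SE of log2 0.248) and Ifit3 3.39-fold (SE of log2 0.251). Ifi27l2a, named by its size of change, rose 6.79-fold (2.88 ± 0.435 against 0.373 ± 0.0523 RPKM, adjusted p = 0.0145), as did Mns1 by 1.51 log2 units (SE 0.302). The developmental transcription factor gene Onecut2 rose from 0.552 ± 0.166 to 1.78 ± 0.631 RPKM (1.56, SE 0.292, adjusted p = 0.0122) and Pax2 from 0 to 206 counts (at least 46.0-fold, adjusted p = 0.0165), and Twist1 lay higher without passing (1.99, SE 0.509). Only these 3 of 42 genes of the Hox and developmental list reached the expression minimum, Pax2 through its R6/2 libraries alone. Camera tested the list on these 3 genes, and it is among the 18 lists that passed in this comparison. With so few members it is not read as a shift of the list as a whole.

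The largest falls in cortex were of genes with low RPKM. Rspo1, a Wnt pathway agonist, fell 10.6-fold (0.417 ± 0.0760 against 3.92 ± 0.985 RPKM, adjusted p = 0.00064), Jsrp1 9.39-fold (adjusted p = 0.0014), Ier5l 9.29-fold, Krt80 12.9-fold, Ntn5 7.44-fold, Rnf39 by 3.33 log2 units (SE 0.506) and 1700001O22Rik by 3.07 (SE 0.428). C1ql2, a synapse organiser, fell 15.9-fold with uneven control libraries (1.33, 0.417 and 7.70 RPKM in wild type replicates 1, 2 and 3; adjusted p = 0.0355). Ttr, the thyroid hormone carrier made by choroid plexus, had 4.29, 7.42 and 131 RPKM in R6/2 replicates 1, 2 and 3 against 1.92 ± 0.938 and did not pass (4.51, SE 1.2, adjusted p = 0.0573; it passed without R6/2 replicate 1 or without R6/2 replicate 2). The other choroid plexus genes did not pass either (median of 3 genes 1.83, all 3 higher when adjusted over the list alone). Choroid plexus genes had camera adjusted p = 0.0118 and adjusted p = 0.161 with an estimated correlation.

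Enzymes that set H3K4 methylation, the subject of the series title, showed small shifts. The 5 demethylase genes lay higher and none passed (none when adjusted over the list alone), with Kdm5c at 15.2 ± 0.609 against 10.3 ± 1.69 RPKM (0.43, SE 0.146, adjusted p = 0.141). H3K4 demethylases had a median of 0.30 log2 units, with camera adjusted p = 0.0448 and adjusted p = 0.236 with an estimated correlation. The methyltransferase list did not pass (camera adjusted p = 0.0827). Lists of microglia (0.767), oligodendrocyte precursors (0.729), vessels (0.462), meninges (0.185), thalamus (0.0871) and blood (0.0871) did not pass either. Nor did those of heat shock (0.767), unfolded protein response (0.557, median and mean of opposite sign), mitochondrial respiration (0.813), REST targets (0.0871, with Vgf lower at -0.91, and no longer passing at -0.48 after GC and length correction), p53 response (0.877, with Cdkn1a lower at -1.30 and median and mean of opposite sign) and histones without a poly(A) tail (0.926).

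Across 11769 genes in cortex at 12 weeks, 84 were higher and 453 lower with edgeR. Genes with an unadjusted p under 0.05 numbered 2087 where 588 were expected, and 270 of the 537 differed at least 2-fold. DESeq2 gave 202 higher and 750 lower, limma 76 and 163, and scaling to the authors' total 119 and 244, so that the lower share went from 84.4 to 67.2%. That scaling raised the median log2 fold change of all genes to 0.139 in cortex and 0.135 in striatum at 12 weeks, and to 0.169 in cortex at 8 weeks; limma on RPKM gave 0.138, 0.140 and 0.170. Groups did not overlap for 3259 genes (27.7%, where 10% were expected by chance). Leaving out a library passed 205 genes (without wild type replicate 1), 275 (wild type replicate 2), 276 (R6/2 replicate 2), 233 (R6/2 replicate 3) or 858 (R6/2 replicate 1). Removal of the GC and length trends passed 665, 187 of them higher (484 among the 537, lower share 71.9%). Cortex-enriched genes fell as a set, 30 of 77 (39.0% against 3.85% of all genes; median log2 fold change -0.68, camera p = 4.56e-23, p = 0.0166 with an estimated correlation, fry p = 0.00204). Of 102 striatum-enriched genes 7 fell and 1 rose (median -0.17, camera p = 0.0135, p = 0.531 with an estimated correlation). The rise was Onecut2, and the falls were Ryr1, Scn4b, Kcnh4, Ppp1r1b, Penk and, named after their values were seen, Car12 (-1.67) and Peg10 (-0.70).

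**Figure D3:**
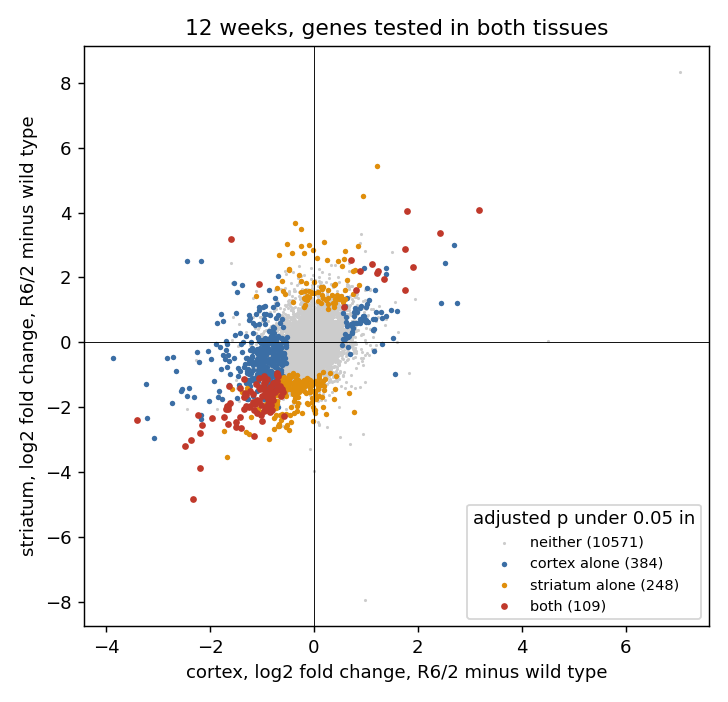
Log2 fold change (R6/2 over wild type) at 12 weeks in cortex, on the horizontal axis, against striatum, on the vertical axis. Each point is a gene tested in both tissues, coloured by whether it passed in cortex alone (384 genes), in striatum alone (248), in both (109) or in neither (10571).

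In striatum at 8 weeks Egr2 was the only gene to pass, at 0.364 ± 0.00314 against 4.42 ± 0.830 RPKM (11.9-fold lower, log2 fold change -3.57, SE 0.335, adjusted p = 0.0335, n = 3 per group). Many genes that fell at 12 weeks lay lower without passing. Penk lay at 155 ± 57.8 against 548 ± 201 RPKM (-1.73, SE 0.323, adjusted p = 0.678), Scn4b at 40.3 ± 24.1 against 151 ± 35.4 (-1.85, SE 0.468), Pde10a at 29.5 ± 13 against 72.9 ± 23.6 (-1.22, SE 0.344) and Drd1 at -1.35 (SE 0.436), without overlap between genotypes. Ppp1r1b (-0.50, SE 0.426), Drd2 (-0.34, SE 0.406), Bdnf (-0.63, SE 1.02), Htt (0.35, SE 0.307), Gfap (0.17, SE 0.275) and Kdm5c (0.56, SE 0.302) did not pass either.

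Several lists passed with camera in R6/2 striatum at 8 weeks, none of them with an estimated correlation. Of 27 shared striatal genes 26 lay lower (none passed, 4 when adjusted over the list alone), including Arpp19 (-1.72, SE 0.375; -1.09 after GC and length correction) and Ryr1 (-1.56, SE 0.378). Shared striatal genes had a median of -0.63 log2 units, with camera adjusted p = 2.1e-11 and adjusted p = 0.402 with an estimated correlation. All 5 indirect pathway genes lay lower (1 when adjusted over the list alone, Penk; camera adjusted p = 0.0024, and adjusted p = 0.402 with an estimated correlation), and the direct pathway list did not pass (0.0524). Immediate early genes lay lower in 16 of 18 (Egr2 passed, 2 when adjusted over the list alone), with Egr1 at 26.0 ± 4.42 against 53.4 ± 8.53 RPKM. Immediate early genes had a median of -0.62 log2 units, with camera adjusted p = 1.64e-05 and adjusted p = 0.264 with an estimated correlation. Neuropeptides (4 of 15 when adjusted over the list alone) included Nts at 5.69 ± 1.57 against 15.2 ± 0.747 RPKM and Crh at -2.82 (SE 0.611). Neuropeptides had a median of -0.80 log2 units, with camera adjusted p = 0.000645 and adjusted p = 0.208 with an estimated correlation. Calcium signalling genes lay lower in 20 of 22 (none when adjusted over the list alone). Calcium genes had a median of -0.51 log2 units, with camera adjusted p = 1.64e-05 and adjusted p = 0.270 with an estimated correlation.

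Smaller shifts passed with camera in this tissue too: interneurons (median -0.58, adjusted p = 0.000103, and adjusted p = 0.208 with an estimated correlation), potassium channels (-0.44, 0.00159, and adjusted p = 0.402 with an estimated correlation), GABA receptors (-0.44, 0.0112, and adjusted p = 0.441 with an estimated correlation) and glutamate receptors (-0.33, 0.0141, and adjusted p = 0.252 with an estimated correlation). Circadian genes (-0.22, 0.0218, and adjusted p = 0.495 with an estimated correlation), astrocytes (-0.19, 0.0177, and adjusted p = 0.402 with an estimated correlation) and cholesterol synthesis (-0.16, 0.0141, and adjusted p = 0.252 with an estimated correlation) did so by smaller medians. The interferon response lay higher in all 8 genes, for example Ifit3 (1.10, SE 0.365). Interferon genes had a median of 0.87 log2 units, with camera adjusted p = 1.23e-05 and adjusted p = 0.208 with an estimated correlation. H3K4 methyltransferases lay higher in 9 of 11, for example Dpy30 (0.60, SE 0.304). H3K4 methyltransferases had a median of 0.19 log2 units, with camera adjusted p = 0.0370 and adjusted p = 0.402 with an estimated correlation. Choroid plexus genes lay lower in all 9, where Ttr ranged over 12.4, 454 and 25.4 RPKM in R6/2 replicates 1, 2 and 3 against 575 ± 711 in wild type. Choroid plexus genes had a median of -1.39 log2 units, with camera adjusted p = 0.0102 and adjusted p = 0.612 with an estimated correlation.

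Lists of other cells did not pass in striatum at 8 weeks, namely cortical projection neurons (camera adjusted p = 0.685), reactive astrocytes (0.291), microglia (0.910), myelin (0.468), oligodendrocyte precursors (0.349), vessels (0.309), meninges (0.592) and thalamus (0.245). The same held for heat shock (0.419), unfolded protein response (0.902), mitochondrial respiration (0.910), H3K4 demethylases (0.434), REST targets (0.793), p53 response (0.842) and histones without a poly(A) tail (0.793). Of 11142 genes, 571 had an unadjusted p under 0.05 (172 higher, 399 lower) where 557 were expected. For comparison, limma passed 1 gene and DESeq2 3 higher and 30 lower. Egr2 was lost on leaving out any library other than wild type replicate 1 (without it 1 gene passed), which differed from the other 5 in the share of reads in genes and in GC correlation (-0.562 against -0.276 to 0.382). Groups did not overlap for 1044 genes (9.37%, where 10% were expected by chance). Of 174 striatum-enriched genes 155 lay lower (median log2 fold change -0.65, camera p = 4.94e-25, p = 0.0738 with an estimated correlation), and the 151 cortex-enriched genes did not pass (-0.01, camera p = 0.954).

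In cortex at 8 weeks no gene passed (smallest adjusted p 0.12 with edgeR). Gad1 lay at 48.0 ± 4.64 against 118 ± 45.0 RPKM (-1.48, SE 0.312, adjusted p = 0.12), Vip at 17.2 ± 3.19 against 38.5 ± 10.3 (-1.37, SE 0.296) and Bdnf at 4.81 ± 0.551 against 10.6 ± 2.28 (-1.32, SE 0.293, adjusted p = 0.123), with n = 3 per group. Irf7 lay higher at 2.35 ± 1.42 against 0.225 ± 0.140 RPKM (3.02, SE 0.643, adjusted p = 0.12), and Gm12695 had 283 counts against 1 (adjusted p = 0.12). Penk (-1.65, SE 0.512, without overlap between genotypes), Drd1 (-1.51, SE 0.514), Pde10a (-0.94, SE 0.452) and Ppp1r1b (-0.59, SE 0.327) also lay lower without passing, and Htt (-0.09, SE 0.348), Drd2 (0.00, SE 0.739), Gfap (-0.22, SE 0.540) and Kdm5c (0.28, SE 0.244) did not pass. Removal of the GC and length trends moved Bdnf to -0.56 (SE 0.226, adjusted p = 0.325) and Vip to -0.89, and Ppp1r1b the other way, to -1.57.

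With camera, 10 lists passed in cortex at 8 weeks. GABA receptor genes lay lower in 12 of 14 (8 when adjusted over the list alone), with Gabrg1 at 4.01 ± 0.516 against 11.7 ± 4.68 RPKM (-1.74, SE 0.371; -0.67 after GC and length correction). GABA receptors had a median of -0.86 log2 units, with camera adjusted p = 9.14e-05 and adjusted p = 0.421 with an estimated correlation. Calcium signalling genes lay lower in 21 of 22 (3 when adjusted over the list alone), with Plcb1 at 38.7 ± 4.96 against 84.4 ± 12.7 RPKM (-0.69 after that correction). Calcium genes had a median of -0.55 log2 units, with camera adjusted p = 9.14e-05 and adjusted p = 0.439 with an estimated correlation. Potassium channels (5 of 18 when adjusted over the list alone; -0.73, 0.000433, and adjusted p = 0.421 with an estimated correlation) included Kcnv1 (-1.46, SE 0.280; -0.70 after GC and length correction). Glutamate receptors (1 of 15 when adjusted over the list alone; -0.59, 0.00185, and adjusted p = 0.551 with an estimated correlation) included Gria3 (-1.24, SE 0.286; -0.41 after that correction). Shared striatal genes (4 of 26 when adjusted over the list alone; -0.69, 0.00185, and adjusted p = 0.551 with an estimated correlation) included Arpp19 at 306 ± 69.1 against 651 ± 127 RPKM. Direct pathway genes (4 of 7 when adjusted over the list alone; -1.02, 0.0302, and adjusted p = 0.551 with an estimated correlation) included Tac1 (-1.57, SE 0.517).

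Interneurons (5 of 15 when adjusted over the list alone; -1.15, 0.00508, and adjusted p = 0.421 with an estimated correlation) included Reln (-1.69, SE 0.330). Neuropeptides (6 of 16 when adjusted over the list alone; -1.13, 0.0170, and adjusted p = 0.551 with an estimated correlation) included Scg2 (-1.26, SE 0.320). Astrocytes (3 lower and 1 higher of 15 when adjusted over the list alone; -0.41, 0.0261, and adjusted p = 0.597 with an estimated correlation) included Gja1 (-1.26, SE 0.248; -0.67 after GC and length correction) and Aqp4 (-1.40, SE 0.293; -0.63 likewise). All 10 interferon genes lay higher (6 when adjusted over the list alone; 1.15, 0.000433, and adjusted p = 0.551 with an estimated correlation), for example Ifit3 (1.12, SE 0.327) and Oasl2 (1.21, SE 0.393). Other cell and activity lists did not pass, namely indirect pathway (camera adjusted p = 0.153), cortical projection neurons (0.0731), immediate early genes (0.131), reactive astrocytes (0.778), microglia (0.448), myelin (0.153), oligodendrocyte precursors (0.177), vessels (0.586), meninges (0.131), choroid plexus (0.184), thalamus (0.201) and blood (0.239). Lists of cell function that did not pass were cholesterol synthesis (0.131), heat shock (0.910), unfolded protein response (0.352), mitochondrial respiration (0.355), H3K4 methyltransferases (0.198), H3K4 demethylases (0.778), REST targets (0.778), p53 response (0.483), circadian clock (0.198) and histones without a poly(A) tail (0.177).

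Of 11663 genes in cortex at 8 weeks, 2909 had an unadjusted p under 0.05 (1396 higher, 1513 lower) where 583 were expected. Here limma also passed none, whereas DESeq2 passed 363 higher and 710 lower and a single fit over 24 libraries 372 and 402. Without wild type replicate 3, edgeR passed 1369 higher and 1485 lower. Fold changes followed GC content (Spearman correlation 0.647), since wild type replicates 1 and 2 had less of the GC-rich genes (-0.617 and -0.606) and wild type replicate 3 did not (0.0857), nor did R6/2 (0.265, 0.336 and 0.215). Groups did not overlap for 2691 genes (23.1%, where 10% were expected by chance). Of 132 striatum-enriched genes 106 lay lower (median log2 fold change -0.66, camera p = 1.4e-08, p = 0.253 with an estimated correlation), and the 226 cortex-enriched genes moved little (-0.12, camera p = 0.205).

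**Figure D4:**
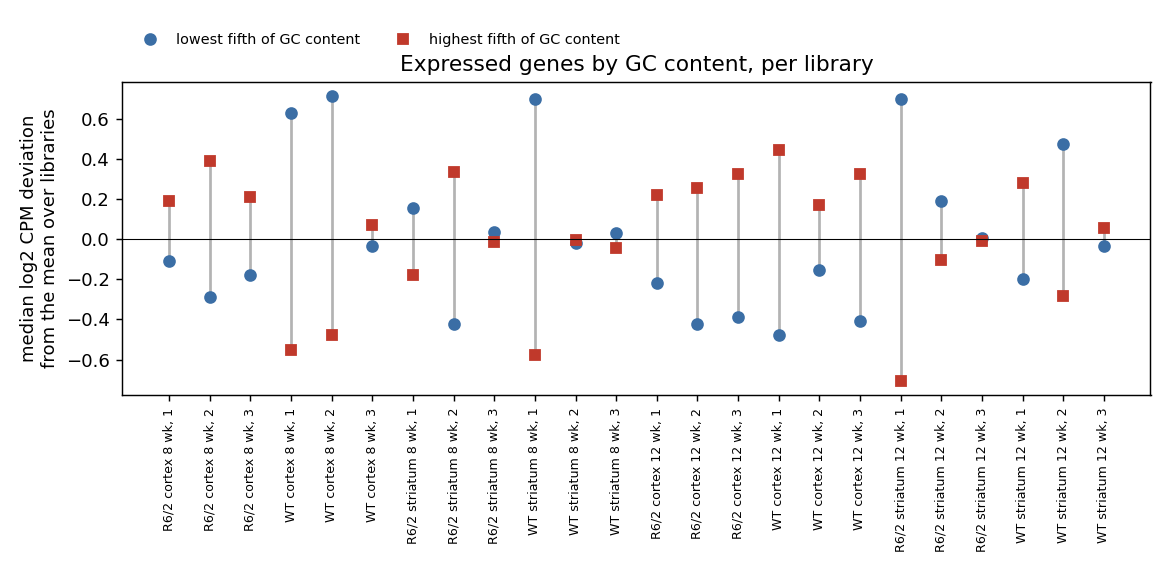
Median deviation of each library's log2 CPM from the mean over libraries (vertical axis), for expressed genes in the lowest (blue circles) and highest (red squares) 20% of GC content, with a line joining both. Wild-type cortex at 8 weeks replicates 1 and 2 have the blue circle above 0 and the red square below it, while replicate 3 and the R6/2 cortex libraries of that age do not.

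Genes changed in R6/2 cortex and striatum at 12 weeks overlapped more than independent calls would. Of 11312 genes tested in both, 93 fell in both tissues (9.71 expected) and 14 rose in both (0.633 expected), and 2 moved in opposite directions. Those 2, Tafa1 (-1.59 in cortex, 3.17 in striatum) and Kcnj16 (-1.05, SE 0.210, adjusted p = 0.0168 in cortex and 1.80, adjusted p = 0.0403 in striatum), were named after their values were seen. Ryr1 (-2.36 in cortex, -3.03 in striatum), Scn4b (-2.19, -3.89), Egr2 (-2.32, -4.85), Kcnh4 (-2.49, -3.21), Rspo1 (-3.40, -2.39), Arc (-1.96, -2.33), Dbp (-1.70, -2.05), Gabrd (-1.42, -2.32) and Slc1a2 (-0.86, -2.08) were among the shared falls, and Usp18, Oasl2, Ifit1 and Ifit3 among the shared rises. Log2 fold changes over all genes correlated with r = 0.403 (Spearman 0.340), and 82.4% of the genes that passed in striatum had the same sign in cortex (61.0% of all genes). The 107 shared genes became 14 without R6/2 striatum replicate 2, 47 without R6/2 striatum replicate 1, 49 without wild-type striatum replicate 3, 59 without R6/2 cortex replicate 3 or wild-type cortex replicate 1, 69 without wild-type cortex replicate 2 and 71 without wild-type striatum replicate 1. Genes are not independent of each other, so these correlations carry no p-value.

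Between ages the fold changes matched less, although with the GC and length correction cortex at 8 and 12 weeks correlated at 0.425 and both tissues at 12 weeks at 0.388. Genes that passed in cortex at 12 weeks had the same sign at 8 weeks in 72.3% of cases (57.6% of all genes, r = 0.261), and those that passed in striatum at 12 weeks in 77.9% (45.1% of all genes, r = 0.00584). The fold changes of cortex and striatum at 8 weeks correlated with r = 0.547 (Spearman 0.589), which fell to 0.290 without wild-type striatum replicate 1. That library and wild-type cortex replicates 1 and 2 had a like GC trend (correlations -0.562, -0.617 and -0.606), and the GC and length correction gave r = 0.410. Since 4 sample numbers occur in both tissues at 8 weeks, these 2 comparisons may not be independent. Leaving out a library also took r for cortex between ages to 0.123 (without wild-type cortex at 8 weeks replicate 3), and that for striatum between ages to -0.189 (without R6/2 at 8 weeks replicate 1) or 0.214 (without R6/2 at 12 weeks replicate 1). Across tissue and age, 8-week striatum against 12-week cortex gave r = 0.243 (73.8% against 59.1%; 0.158 without wild-type cortex replicate 2) and 8-week cortex against 12-week striatum r = -0.00791 (63.5% against 44.8%; -0.168 without wild-type striatum replicate 2, 0.176 without R6/2 striatum replicate 1).

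The genotype effect on several genes differed between tissues at 12 weeks, when the tissue by genotype interaction passed 26 genes higher and 12 lower in striatum relative to cortex. Tafa1, a secreted brain protein, fell in R6/2 cortex (3.53 against 9.68 RPKM) and rose in striatum (4.12 against 0.417), an interaction of 4.77 log2 units (SE 0.469, adjusted p = 0.000341, n = 3 per group). Adcy5, the adenylyl cyclase of striatal neurons, was level in cortex (28.2 against 26.2 RPKM) and fell in striatum (34.7 against 170), with an interaction of -2.40 (SE 0.337, adjusted p = 0.0164). Strn did likewise (-1.81, SE 0.266, adjusted p = 0.0200), while Grik1 (3.35, SE 0.518, adjusted p = 0.0246) and Gng4 (1.84, SE 0.289, adjusted p = 0.0246) gained more in striatum. Lists that differed with camera were shared striatal genes (median -1.26, adjusted p = 1.54e-23, and adjusted p = 0.295 with an estimated correlation), indirect pathway (-1.70, 0.00192, and adjusted p = 0.349 with an estimated correlation) and direct pathway (-0.68, 0.0485, and adjusted p = 0.497 with an estimated correlation). So did calcium signalling (-0.52, 8.07e-06, and adjusted p = 0.349 with an estimated correlation), immediate early genes (-0.44, 0.0105, and adjusted p = 0.574 with an estimated correlation), glutamate receptors (-0.60, 0.0144, and adjusted p = 0.349 with an estimated correlation) and thalamus markers (1.12, 0.0087, and adjusted p = 0.349 with an estimated correlation).

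Of 11768 genes in this interaction, 1234 had an unadjusted p under 0.05 where 588 were expected, limma, which had been planned for this test, passed 1 (Tafa1), and a single fit over 24 libraries passed none. Leaving out a library passed 1 gene (wild-type cortex replicates 1 or 3, R6/2 striatum replicate 2, or wild-type striatum replicate 3), 3 (R6/2 cortex replicate 3), 6 (R6/2 cortex replicate 2), 8 (wild-type cortex replicate 2), 12 (R6/2 cortex replicate 1), 24 (wild-type striatum replicate 2), 75 (wild-type striatum replicate 1) or 107 (R6/2 striatum replicate 3). Tafa1 passed each time.

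No gene passed in the other interactions. At 8 weeks the tissue by genotype interaction had 417 of 11514 genes at an unadjusted p under 0.05 (576 expected; limma 0; smallest adjusted p 0.944 with edgeR), with Ebf4 (-2.64), Nt5e (2.11), Heatr6 (-1.17), Otof (2.14) and Htr2a (2.39) first. The age by genotype interaction in cortex had 2088 of 11742 (587 expected; limma 0; smallest adjusted p 0.163), with A730069N07Rik (2.92), Tnfrsf25 (-3.56), Ldhd (-2.06), Rgl2 (-1.61) and H2aj (-2.51) first, and without wild-type cortex at 8 weeks replicate 3 it passed 2073 genes. In striatum it had 1349 of 11429 (571 expected; limma 0; smallest adjusted p 0.378), with Vwc2l (3.71), Grik1 (3.63), Steap2 (2.58), Dgkk (6.73) and Ebf4 (2.81) first, and without R6/2 striatum at 8 weeks replicate 1 it passed 23. A larger fall of shared striatal genes with age passed as a list (median -1.25, camera adjusted p = 4.94e-11, and adjusted p = 0.393 with an estimated correlation).

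Wild-type striatum and cortex differed in the genes that mark them, which checks the tissue labels. At 12 weeks Scn4b (398 ± 96.9 against 26.1 ± 1.18 RPKM), Drd1 (86.9 against 4.52), Dach1 (19.6 against 0.870), Slc35d3 (21.4 against 0.991) and Ppp1r1b (1252 against 75.4) were higher in striatum, and Slc17a7, the vesicular glutamate transporter of cortical neurons (20.8 against 125), and Rasgrf2 (1.19 against 19.9) in cortex. Shared striatal genes were 2.62 log2 units higher in striatum at the median (camera adjusted p = 2.98e-28, and adjusted p = 0.134 with an estimated correlation), cortical projection neuron genes 1.47 lower (8.24e-06, and adjusted p = 0.384 with an estimated correlation) and myelin genes 1.29 higher (5.5e-08, and adjusted p = 0.332 with an estimated correlation). At 12 weeks 1316 of 11715 genes were higher and 1336 lower in striatum with edgeR, and the total of 2652 became 1060 without wild-type cortex replicate 1, 1720 without wild-type cortex replicate 2, 1445 without wild-type cortex replicate 3 and 1478 without wild-type striatum replicate 3. At 8 weeks 250 of 11479 were higher and 222 lower, among them Scn4b (151 against 18.3 RPKM), Pde1b (135 against 28.7), Scube3 (5.52 log2 units), Lhx8 (7.51) and Ptprv. That count became 101 without wild-type striatum replicate 3, 115 higher and 60 lower without wild-type striatum replicate 2, 985 without wild-type striatum replicate 1, 132 without wild-type cortex replicate 1 and 189 without wild-type cortex replicate 2. In limma 163 higher and 1548 lower genes passed, with a median log2 difference of -0.598 over all genes.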

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

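All tests of explanations given here were chosen only after the results were seen, except that for tissue of the hypothalamus and the regroupings of samples, and the tests of differences between tissues and ages, which were fixed in advance with limma and made with edgeR once counts were seen.

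The fall of striatum-enriched genes in R6/2 striatum at 12 weeks was weighed against technical causes, since R6/2 replicate 1 stood apart and the libraries differed in GC content. Of the 58 striatum-enriched genes that fell, 58 still fell after each library's trend on GC content and length was removed, which argues against a GC bias. A smaller share of striatal tissue in the R6/2 samples, acting alone, would lower genes of striatal neurons alike. With the same correction, 47.8% of the 67 genes enriched at least 8-fold lay more than 2 SE from their median of -1.66. Of them 20 lay above it and 12 below, and all 67 ranged from -6.50 to 4.27. These 67 included choroid plexus genes, such as Ttr (-0.13, SE 0.442) and Clic6 (0.95, SE 0.415), whose amount need not follow striatal tissue. The spread therefore cannot decide whether a smaller share of striatal tissue contributed to the fall. R6/2 replicate 1 alone did not carry the fall, as the median of the set without it was -1.27, with 30 genes lower. Loss or silencing of projection neurons in R6/2 was not told apart by these data.

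The 102 genes higher in R6/2 striatum at 12 weeks included markers of neighbouring regions, so the same causes were weighed. After the GC and length trends were removed 98 were still higher, which argues against a GC bias. Without R6/2 replicate 1 a test of all genes passed 36 as higher, 33 of them among the 102, which argues against that library alone for those 33 and leaves it open for the other 69. Tissue from the hypothalamus was tested with 34 marker genes, of which 31 matched, 9 were tested, 8 lay higher and 0 passed, and their median of 0.92 (0.83 after GC correction) could not tell, since it lay between the bounds written in advance. The most abundant of them, Peg10 (32.9, 6.07 and 2.35 RPKM in R6/2 replicates 1, 2 and 3 against 4.96, 1.56 and 3.57 in wild type) and Ecel1 (7.22, 4.83 and 3.12 against 8.05, 5.63 and 8.60), were also read in wild-type striatum, and neither passed, and Tac2, Trh, Lhx1 and Prlr of the list also stood in other lists.

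The 2854 genes that passed in cortex at 8 weeks without wild type replicate 3 were weighed as the other large pattern. After the GC and length trends were removed 76 passed (20 higher and 56 lower, 62 of them among the 2854), and the Spearman correlation of fold change with GC content went from 0.704 to 0.0321, so a GC bias of the other wild-type libraries could account for most of them. An effect of genotype shared with 12 weeks stays open: 58.1% of the 2833 genes tested at both ages had the same sign at 12 weeks (55.4% of all genes), but a GC bias in most of these calls would hold that share near the share of all genes. With all libraries 72.3% of the genes that passed in cortex at 12 weeks had the same sign at 8 weeks, and with GC and length correction the fold changes of both ages correlated at 0.425. An effect of genotype present at 8 weeks alone stays open as well.

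Differences between tissues or ages were tested as differences, with edgeR for genes and with camera at its preset correlation for lists. At 12 weeks 38 genes differed between tissues in their genotype effect with edgeR (limma passed Tafa1 alone), with Tafa1 (4.77), Adcy5 (-2.40), Strn (-1.81), Grik1 (3.35) and Gng4 (1.84) first. Cortex and striatum of that age bore separate runs of sample numbers, so a difference other than tissue is not excluded. At that age the lists of shared striatal genes (-1.26), direct pathway (-0.68), indirect pathway (-1.70), immediate early genes (-0.44), thalamus (1.12), calcium signalling (-0.52) and glutamate receptors (-0.60) also passed in the test between tissues. At 8 weeks no gene passed between tissues, and 417 had an unadjusted p under 0.05 where 576 were expected. The lists that passed there were cortical projection neurons (median 0.44), myelin (-0.57), oligodendrocyte precursors (0.47), choroid plexus (-3.11), glutamate receptors (0.25) and GABA receptors (0.46). A difference between tissues at 8 weeks was therefore not established. Between ages no gene passed in either tissue, and in cortex the list of myelin genes did (-0.96). In striatum the lists that passed between ages were shared striatal genes (-1.25), indirect pathway (-1.34), immediate early genes (-1.01), myelin (-0.34), calcium signalling (-0.84), potassium channels (-0.53), the interferon response (0.97) and the circadian clock (-0.60). None of these lists passed with an estimated correlation (adjusted p from 0.295 to 0.942).

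Samples were also regrouped against their labels. For each genotype or tissue comparison there are 10 splits of the samples, too few for a test. The real grouping gave 537 genes in cortex and 384 in striatum at 12 weeks, and the other splits gave at most 0, so the true split stood alone (1 of 10 for each). At 8 weeks cortex gave 0 with all 10 splits at 0, and striatum gave 1 where the highest other split gave 4 (2 of 10 at or above it). Wild-type tissues gave 2652 at 12 weeks (1 of 10, highest other 0), and at 8 weeks 472 where another split gave 1869 (2 of 10). That split set cortex replicates 1 and 2 and striatum replicate 1 (GC correlations -0.617, -0.606 and -0.562) against the other wild-type libraries (0.0857, 0.0187 and -0.0377). This points to a structure of these samples other than tissue, one that followed their GC trend. Lists passing numbered 10 in cortex at 8 weeks (5 of 10 splits had as many, highest other 21), 15 in striatum at 8 weeks (1 of 10, 13), 18 in cortex at 12 weeks (1 of 10, 16) and 13 in striatum at 12 weeks (1 of 10, 11). The 18 include the Hox and developmental list, which had too few genes above the expression minimum to be read. Interactions had 100 splits. The age interactions gave 0 in cortex (100 of 100, highest 738) and in striatum (100 of 100, highest 134), and the tissue interaction gave 0 at 8 weeks (100 of 100, highest 14). The tissue interaction at 12 weeks gave 38, which 4 of 100 splits reached, and a split with 352 points to a structure of the samples there too.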

How the results depend on the processing

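Among the tests of other processing, scaling to the authors' library total, both GC corrections, the offset for deposited gene lengths and the fit of log2 CPM without a block were chosen only after the results were seen, and the others were fixed in advance, limma at a pseudocount of 0.5 as the test first planned for the interactions and the wild-type tissues. In both tissues at 12 weeks, the genes that passed kept their direction under every alternative, but their number did not hold. No named gene that passed reversed: 22 of 73 in cortex and 4 of 64 in striatum passed under all alternatives, and 51 and 60 were lost under some of them. The fall of striatum-enriched genes in striatum at 12 weeks (median -1.13 to -1.65) and of cortex-enriched genes in cortex (-0.60 to -0.96) kept its direction and side of the threshold throughout. The correlation of both tissues at 12 weeks stayed between 0.332 and 0.413 with each library left out. The tissue by genotype interaction at 8 weeks gave 0 genes in all settings. With 3 libraries per group small changes are missed: at 8 weeks the simulation recovered 10.4% of 2-fold changes in cortex and 13.4% in striatum. Depth limits genes with few reads most in striatum at 8 weeks, where the smallest library had 7.09 M counts in genes. Leaving out a library leaves a group of 2, so its spread rests on both groups together, and fewer samples lower the number that can pass. For the changes listed below the cause was not tested.

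Where edgeR gave 537 genes in cortex and 384 in striatum at 12 weeks, 38 in their interaction and 107 shared, limma at a pseudocount of 0.1 gave 218, 5, 1 and 2. At a pseudocount of 1 it gave 243, 9, 1 and 5, and at 0.5 it gave 239, 10, 1 and 6. DESeq2 gave 952, 765 and 225 shared, with 1073 in cortex (edgeR 0) and 33 in striatum (edgeR 1) at 8 weeks. A single fit over 24 samples gave 98, 957, 0 and 39, with 774 and 3 at 8 weeks. Scaling to the authors' total gave 215 in striatum, 17 in the interaction and 50 shared. Quantile normalization gave 66 shared and 0 in striatum at 8 weeks. GC correction gave 707 in striatum and 151 in the interaction, and GC and length correction 730, 165 and 161 shared. For wild-type tissues at 8 weeks (472 genes) limma gave 1666 at a pseudocount of 1 and 1711 at 0.5, and GC and length correction 1021.

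Without each library in turn, the genes passing ranged over 0 to 2854 in cortex and 0 to 1 in striatum at 8 weeks, and over 205 to 858 and 42 to 469 at 12 weeks. The age interactions ranged over 0 to 2073 in cortex and 0 to 23 in striatum, the tissue interaction at 12 weeks over 1 to 107, wild-type tissues over 101 to 985 at 8 and 1060 to 3485 at 12 weeks, and shared genes over 14 to 139.

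With an estimated correlation camera passed 0 lists in each genotype comparison (10, 15, 18 and 13 with the preset), and the fall of striatum-enriched genes in striatum at 8 weeks (-0.65) no longer passed. With GC and length correction 17 lists passed in cortex at 8 weeks, and the cortex-enriched genes there passed at -0.27. That correction gave correlations of fold changes of 0.410 for cortex and striatum at 8 weeks, 0.425 for cortex at 8 and 12 weeks, 0.20 for 8-week cortex and 12-week striatum, 0.330 for 8-week striatum and 12-week cortex and 0.147 for striatum at 8 and 12 weeks. Without the correction they were 0.547, 0.261, -0.00791, 0.243 and 0.00584, and leaving out each library gave ranges of 0.290 to 0.587, 0.123 to 0.329, -0.168 to 0.176, 0.158 to 0.296 and -0.189 to 0.214 in the same order.

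Reversals were confined to named genes that had not passed. In cortex at 8 weeks Drd2 went from 0.00 to -0.11, -0.0294 and -0.0558 with limma at pseudocounts of 0.1, 1 and 0.5, -0.00845 with no filter, -0.0378 with median-of-ratios, -0.14 with quantile scaling, -0.19 with DESeq2, -0.37 with GC and -0.54 with GC and length correction, and ranged over -1.16 to 0.52 without each library. There Htt reached 0.0220, 0.0251 and 0.0238 with the same limma fits, 0.0352 with the authors' total and 0.0341 with GC and length correction (-0.33 to 0.21 without each library), and Gfap 0.15, 0.14 and 0.14 with limma (-0.56 to 0.78). Ranges without each library also crossed 0 for Drd2 (-0.84 to 0.0189) and Bdnf (-2.38 to 0.56) in striatum at 8 weeks, Drd1 in cortex at 12 weeks (-0.76 to 0.18), and Bdnf (-0.0598 to 0.81) and Kdm5c (-0.35 to 0.0326) in striatum at 12 weeks.

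At 8 weeks 4 numbers in the sample titles occur in both tissues. With the number as a random block (12 samples, consensus correlation 0.263) or a fixed block (8 samples) the interaction passed 0 genes, as it did with no replicate block. Samples with the same number correlated at -0.0511, 0.0912, 0.346 and 0.486, and not every sample correlated best with its own number (an R6/2 cortex sample at 0.126 and a wild-type striatum sample at 0.459 did so with another), so the numbers were not taken to pair the samples. A block was not run for the other results.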

Other observations

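None of the tests below was fixed before the data were examined, and the genes named here were chosen after their values were seen.

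Genes outside the fixed lists fell in both tissues of R6/2 mice at 12 weeks. Ddit4l, an inhibitor of mTOR signalling, fell by 2.19 log2 units in cortex (SE 0.287, adjusted p = 0.00243) and by 2.82 in striatum (SE 0.348, adjusted p = 0.00249). Epor, the erythropoietin receptor, fell by 2.23 in each (SE 0.311 and 0.393), and Hrh3, the histamine H3 receptor that restrains transmitter release, by 1.72 and 2.31 (SE 0.195 and 0.436). Among genes higher in both, Scn9a, a voltage-gated sodium channel, rose by 1.90 in cortex (SE 0.395, adjusted p = 0.0209) and 2.31 in striatum (SE 0.486, adjusted p = 0.0228). Gng4, a G protein subunit, rose by 0.72 and 2.55 (SE 0.158 and 0.273). Interferon-linked genes not on the list rose as well, Lgals3bp by 1.22 and 2.13 (SE 0.265 and 0.381) and Irgm1 by 0.89 and 2.21 (SE 0.194 and 0.459).

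Rpl38, a ribosomal protein gene, had counts only in the 3 libraries with the shorter deposited gene lengths, at 7.15 RPKM in R6/2 cortex at 8 weeks replicate 3, 5.32 in R6/2 cortex at 12 weeks replicate 2 and 16.6 in R6/2 striatum at 12 weeks replicate 3, and at 0 RPKM in the other libraries of those comparisons.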
